A study of Glycine max with 16 samples.

How the data were processed

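Leaf RNA was measured in soybean (Glycine max) seedlings of 4 lines, of which 3 are transgenic lines over-expressing the transcription factor gene GmWRKY54 (A004A, A005B and B010C) and 1 is the null line without over-expression. Per the labels, the seedlings were 2 weeks old, trifoliate leaves were collected either from watered plants or after 6 h of drying in air, total RNA was purified on RNeasy columns, and libraries were made with an Illumina RNA-seq kit. The labels list 16 samples in 8 groups of 2. Nothing in them says whether the 2 samples of a group came from separate plants.

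The values are RPKM (reads per kilobase of gene, relative to the mapped reads of a library) as the authors deposited them, in a table of 56044 genes. The table holds 8 columns of values, 1 for each line and treatment, so there is 1 value for the 2 samples of a group. Whether and how the authors combined the 2 samples is not given in the sources used here. TopHat is the aligner named per the submitters' processing notes, without a version, and the counting program, genome build and annotation are not given in the sources used here. Each column was tied to its line and treatment by its name, the line given in the labels and the sample titles, and 0 columns were left without a group. The null columns carry the line name B001A, where the titles say Null.

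Depth per column is unknown. Among genes that stayed below 0.3 RPKM in every column, the commonest ratio between a pair of columns was shared by only 0.287% to 3.63% of genes, within 0.003 on the log2 scale over 28 pairs of columns, so 1 step size per column did not turn the values into whole reads, and no count model was used. An exact 0 in such a table can be a failed estimate, and genes are described as listed at 0. Between 19.96% and 23.1% of genes were listed at 0 in each column, and 7091 genes in all of them.

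Genes with at least 1 RPKM in at least 2 columns were kept (34400 genes), and values were used as log2(RPKM + 1). Fold changes on this scale understate the change of genes with low values. The plan made before the data were examined was a linear model over 16 libraries with 2 per group. With 1 column per group it could not be fitted, and the following replaced it. For the mean effect of dehydration, limma was fitted to the 8 columns with terms for line and treatment, which leaves 3 residual degrees of freedom per gene and takes the spread from how the treatment effect varied between the 4 lines. For the 3 transgenic lines against null, limma was fitted with a group mean for null and for the transgenic lines in each treatment (4 residual degrees of freedom). This second fit holds no term for line, and its spread per gene is shared by the watered and dehydrated columns. The lone null column was there assumed to vary as the transgenic lines do, and a difference between null and transgenic plants is a comparison of 1 line with 3. Both fits used empirical Bayes moderation with a trend on mean expression, two-sided tests, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Differences between single columns have no replicate check, carry no p-value and are given as numbers of genes differing at least 2-fold, which is 1 on the log2 scale. To judge how often a line stands apart by itself, each of the other lines was set against the remaining 3 in the same way.

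Comparisons of transgenic lines with null share the null column. Unchanged groups were therefore simulated, with the spread that limma estimated between the transgenic lines, and the overlap of independent lists was computed from the list sizes. Gene lists were compared with 10000 random lists of the same size matched on mean expression, as a description of these columns. The fits were first tested on simulated columns of 34400 genes in which 100 genes were changed 2-fold and 100 others 4-fold. The changed genes were drawn from those with a mean log2 value above 3 in the watered columns. For both fits, the simulated spread was that of the response to drying between the 4 lines. For dehydration, 39% of genes changed 2-fold and 83% of genes changed 4-fold were recovered, with 4 false calls. For transgenic lines against null in watered plants, the shares were 2% and 50%, with 3 false calls. That fit takes its real spread from between lines, so these shares are only a rough guide to it. In the real dehydration fit 68.7% of genes were called, far more than were changed in the simulation. The simulated recovery and false calls for dehydration therefore do not carry over to that result.

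The deposited table does not pair its identifiers with gene names. The gene table at hand, of assembly Glycine_max_v4.0, matched 0 of the identifiers, so genes are given by identifier, 40 gene lists that had been fixed by function could not be built, and no gene set test was run. Named genes were to be those with the largest log2 change among called genes with at least 5 RPKM on the higher side and no overlap between the sides. The further condition that a gene have a description was dropped, and at most 2 genes in each direction are named per comparison. Genes that limma called for null against the 3 transgenic lines are named besides these, also below 5 RPKM. For single columns and where null was compared with the 3 transgenic lines, the 2-fold rule took the place of the call.

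Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, no trend in the spread, a 2-fold minimum on called genes, and only the compared columns in the fit. Leaving out a line was added after the data were seen. Analyses used R 4.3.3 with limma 3.58.1, and plots used Python and matplotlib.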

Results

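Leaves of 4 soybean lines were profiled by RNA sequencing with and without dehydration, to ask what over-expression of GmWRKY54, a member of the WRKY family of plant transcription factors, changes in watered plants and in plants dried in air for 6 h. The values are the authors' RPKM, with 1 value per gene for each of the 8 combinations of line and treatment, where the labels list 2 samples each. There were therefore no replicate values within a group. The number of genes at 1 RPKM or more lay between 28847 in dehydrated B010C and 31333 in watered A004A. The sum of RPKM over genes ranged from 636011 in dehydrated A004A to 818267 in dehydrated B010C, and the number of reads behind each value is unknown. Across genes, the 4 watered columns correlated with each other at Pearson r between 0.967 and 0.981 and the 4 dehydrated columns at 0.942 to 0.979, whereas a watered and a dehydrated column correlated at 0.587 to 0.722.

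The level of the transgene could not be read directly, because the sources used here do not pair gene identifiers with names. Before the data were examined, Glyma.10G011300 had been written down as an identifier that might belong to GmWRKY54, to be used only if a source paired them. None did, so its values do not check the labels. Glyma.10G011300 stood at 11.5 RPKM in watered and 11.7 RPKM in dehydrated null plants. In A004A it stood at 51.1 RPKM watered and 119 RPKM dehydrated, which was 4.46 and 10.2 times the null value. In A005B it stood at 73.0 and 238 RPKM, 6.37 and 20.4 times null. In B010C the values were 9.05 and 18.0 RPKM, 0.790 and 1.55 times null. Glyma.10G011300 and Glyma.01G082900 were the 2 genes of 34400 that lay at least 2-fold above both null and B010C in A004A and A005B in both treatments, a search made after the values had been seen. Glyma.01G082900 was listed at 0 in null and B010C and lay between 1.20 and 6.93 RPKM in A004A and A005B. In limma, the mean of the 3 transgenic lines did not pass for Glyma.10G011300 in watered plants (log2 difference 1.44 ± 1.47 SE, adjusted p = 1) or dehydrated plants (2.69 ± 1.47 SE, adjusted p = 0.421).

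**Figure D1:**
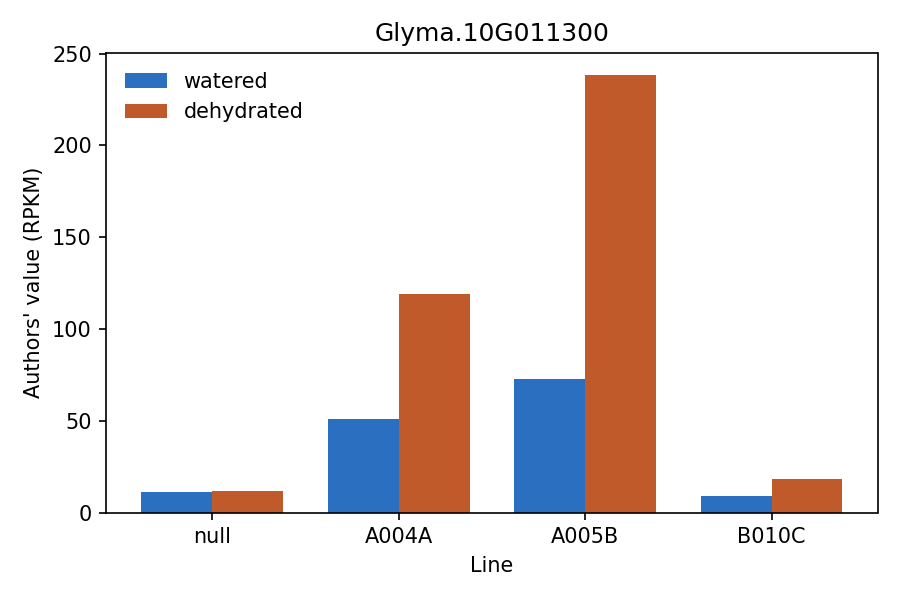
Authors' RPKM of Glyma.10G011300 on a linear axis in each of the 4 lines, watered and dehydrated, 1 bar per column. A004A and A005B lie between 51.1 and 238 RPKM, and null and B010C between 9.05 and 18.0 RPKM.

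Most of the leaf transcriptome differed between leaves dried for 6 h and watered leaves. The labels give no watered group held for the same 6 h, so drying cannot be told apart from the time that passed. Glyma.09G185500 rose from between 1.33 and 5.21 RPKM in the 4 watered lines to between 2161 and 4315 RPKM in the dehydrated lines, a mean log2 change of 9.58 ± 0.31 SE (limma, adjusted p = 7.99e-07). Glyma.01G021000 rose by 9.42 ± 0.27 SE on the log2 scale, from at most 7.22 RPKM to at least 3653 RPKM (adjusted p = 6.32e-07). In the other direction, Glyma.09G231900 fell by 7.63 on the log2 scale (SE 0.32), from 1017 RPKM or more to 11.9 RPKM or less (adjusted p = 1.84e-06), and Glyma.17G212200 fell by 7.27 (SE 0.18), from 297 RPKM or more to 1.79 RPKM or less (adjusted p = 4.23e-07). These changes held their direction in 4 of 4 lines, which was a condition for naming these genes. With limma, 9882 genes were higher and 13764 lower in dehydrated leaves at an adjusted p under 0.05, together 68.7% of the 34400 genes tested. Of these, 5518 and 7571 changed at least 2-fold. The rise and fall were carried by all lines, with 3826 genes at least 2-fold higher and 4665 at least 2-fold lower in each of the 4 lines. Of tested genes, 74.4% moved in the same direction in all 4 lines. The share would be 12.5% if rises and falls were equally likely and independent between lines. A shift common to the dehydrated columns, such as one of scaling, also gives shared directions. Changes of at least 16-fold in every line were mostly rises, with 338 genes higher and 60 lower. With values as deposited, the direction depended on abundance, which was not followed under another scaling or pseudocount. Among genes with a mean under 5 RPKM, 22.2% rose and 43.8% fell, and among those over 100 RPKM, 40.0% rose and 32.6% fell.

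The most abundant transcripts were exchanged. The 10 genes with the highest mean RPKM in watered leaves made up 6.70% to 7.10% of all RPKM in the watered columns and 0.888% to 1.66% in the dehydrated columns, and 9 of the 10 were called lower. The 10 highest genes of dehydrated leaves went from 1.41% to 1.69% of all RPKM up to 4.26% to 5.11%, and 8 of the 10 were called higher. The lists shared 1 gene. The median log2 change of all tested genes was -0.18. Median-of-ratios scaling, which by construction centres it, moved it to 0.01, and quantile normalization moved it to -0.066. The share of higher genes among calls was 41.8% as deposited, 50.3% after median-of-ratios scaling, and 46.7% after quantile normalization, with 11130 genes higher and 12714 lower.

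Every line responded to drying along the same axis, and null responded least. In null, 5439 genes were at least 2-fold higher and 6169 at least 2-fold lower after drying. The numbers were 5749 and 9727 in A004A, 6090 and 8153 in A005B, and 6063 and 8045 in B010C. In null the largest rises among genes of at least 5 RPKM were those of Glyma.03G238800, from 2.52 to 1706 RPKM, and Glyma.01G021000, from 7.22 to 3920 RPKM. The largest falls were those of Glyma.10G200800, from 181 to 0.216 RPKM, and Glyma.04G169600, from 415 to 2.60 RPKM. The log2 responses of any pair of lines correlated across genes at 0.885 to 0.925. Regressed across genes on the mean response of the other 3 lines, the response of null had a slope of 0.83, against 1.04 in A004A, 0.97 in A005B and 1.04 in B010C. These are comparisons of single columns without a replicate check, and genes are not independent replicates. With a mean of at least 5 RPKM the split in null turned to 3962 higher and 3506 lower genes. For A004A the split of 5749 higher and 9727 lower genes became 7772 and 7385 after median-of-ratios scaling and 7259 and 8036 after quantile normalization.

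**Figure D2:**
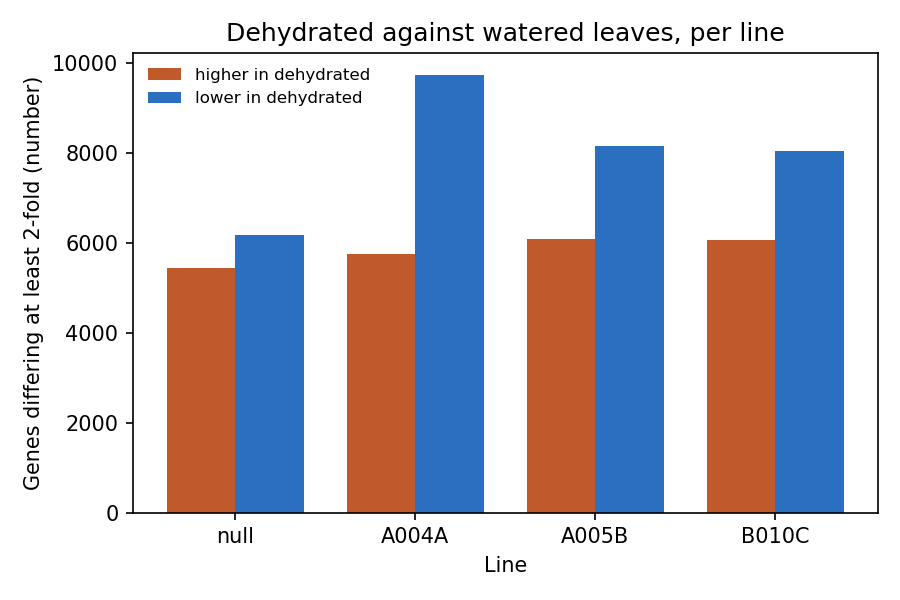
Number of genes at least 2-fold higher or lower in dehydrated than in watered leaves, per line, from 1 column per line and treatment and with values as deposited. Lower genes outnumber higher genes in each line, from 6169 against 5439 in null to 9727 against 5749 in A004A. After median-of-ratios scaling higher genes outnumber lower genes in each line, whereas after quantile normalization lower genes do, from 6000 against 5308 in null to 8036 against 7259 in A004A.

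In watered leaves few genes set the transgenic lines apart from null as a group, in a limma fit with little power. On simulated columns it recovered 2% of genes changed 2-fold and 50% of those changed 4-fold, among genes with a mean watered log2 value above 3. The simulated spread came from the responses and not from between the lines, so these shares are a rough guide. A lack of calls therefore does not show the lines to be alike. The largest differences shared by the 3 lines among genes of at least 5 RPKM were those of Glyma.09G230600, listed at 0 in null and at 13.7 to 26.3 RPKM in the transgenic lines, and Glyma.07G077500, listed at 0 in null and at 7.76 to 21.2 RPKM in the others. Conversely, Glyma.15G252300 stood at 14.2 RPKM and Glyma.01G244000 at 6.14 RPKM in null, and both were listed at 0 in the 3 transgenic lines. None of these 4 passed limma (adjusted p = 1 for each). At least 2-fold differences from null were seen for 292 higher and 531 lower genes in A004A, 355 and 429 in A005B, and 192 and 374 in B010C. In 33 genes all 3 lines were at least 2-fold above null and in 37 all 3 were at least 2-fold below it. Simulated unchanged lines gave 37 and 55 such genes. Limma called 0 genes for the mean of the 3 lines, with 1103 genes, or 3.21% of those tested, at an unadjusted p under 0.05, and 1662, 599 and 460 when A004A, A005B and B010C took the place of null. Set against the remaining 3 lines in the same way, null stood at least 2-fold apart in 70 genes, A004A in 343, A005B in 155 and B010C in 93. Each watered difference from null, and each response of null, rests on the label of the watered null column. For 39 genes the watered null and A005B columns ran against their dehydrated columns, and with these 2 labels exchanged the count for null would be 155.

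In dehydrated leaves the distances between lines were larger. Among genes at least 2-fold apart in all 3 lines and reaching 5 RPKM, the highest mean differences were those of Glyma.14G023800, listed at 0 in null and at 3.17 to 42.4 RPKM in the transgenic lines (adjusted p = 0.353), and Glyma.10G277000, listed at 0 in null and at 5.48 to 29.4 RPKM (adjusted p = 0.312). Glyma.20G122100 stood at 31.1 RPKM in dehydrated null leaves and was listed at 0 in the 3 transgenic lines (adjusted p = 0.0775), and Glyma.17G031100 stood at 18.6 RPKM in null and was likewise listed at 0 (limma, log2 difference -4.29, adjusted p = 0.00484). Limma called 2 genes, both lower in the transgenic lines. The other was Glyma.13G309400, at 3.79 RPKM in null and listed at 0 in the 3 transgenic lines (adjusted p = 0.0212). Because 3 values of 0 have no spread, both calls rest on genes listed at 0. Limma calls were similarly few when A004A, A005B or B010C took the place of null. At an unadjusted p under 0.05 there were 5041 genes, 14.7% of those tested, and 4717, 962 and 1748 when A004A, A005B and B010C took the place of null.

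Against null, 950 genes were at least 2-fold higher and 2786 lower in dehydrated A004A, 980 and 1121 in A005B, and 677 and 339 in B010C. All 3 lines were at least 2-fold above null in 133 genes and below it in 142, against 59 and 59 with simulated unchanged lines. Null was not the line that stood most apart with values as deposited, with 275 genes against 303 for B010C, 171 for A004A and 117 for A005B. With a pseudocount of 0.1 it was, with 918 genes against 655 for A004A, and likewise after quantile normalization, with 262 against 230 for B010C. The direction in A004A and A005B depended on the scaling. After median-of-ratios scaling, 1743 genes were higher and 1381 lower in A004A, 1183 and 856 in A005B, and 1003 and 195 in B010C, and after quantile normalization the splits were 1548 and 1336, 1104 and 849, and 758 and 212. In B010C a pseudocount of 0.1 turned the split to 1187 higher and 1574 lower.

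**Figure D3:**
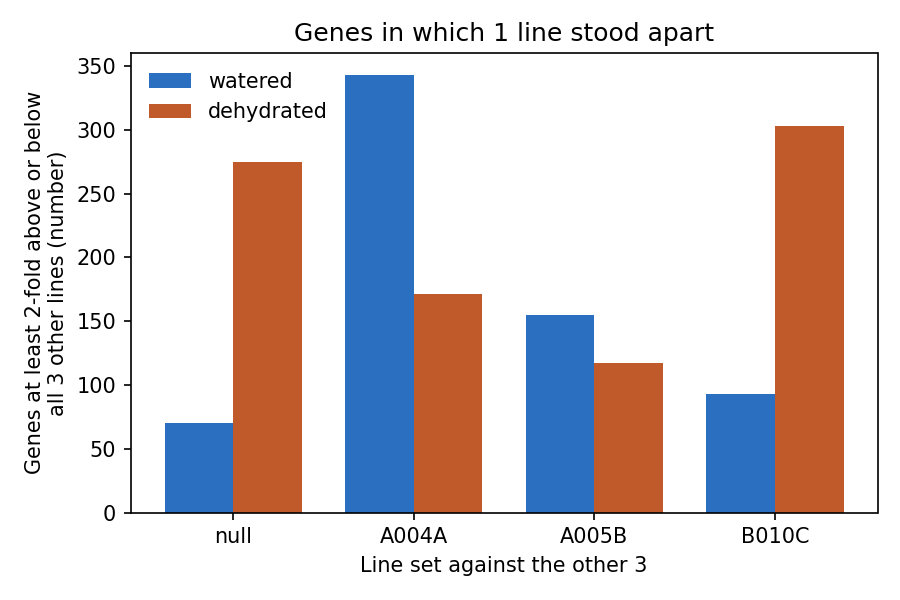
Number of genes in which 1 line lay at least 2-fold above or below all 3 other lines, in watered and dehydrated leaves, from 1 column per line and treatment. With the labels as given, null has 70 genes when watered, the lowest of the 4 lines, and 275 when dehydrated, where B010C has 303.

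Whether over-expression changed the response to drying was asked through the difference between each line's response and that of null. The limma test of this difference did not pair the watered and dehydrated columns of a line. Glyma.15G252300 went from 14.2 to 9.72 RPKM in null on drying, and from a listed 0 to between 16.1 and 71.3 RPKM in the 3 transgenic lines (adjusted p = 0.494). Glyma.10G207000 went from 36.8 RPKM to a listed 0 in null, from 19.1 to 21.9 RPKM in A004A and from a listed 0 to 23.9 RPKM in A005B, and was listed at 0 in B010C in both treatments (adjusted p = 0.534). It is among 39 genes with an uncommon pattern, of which 38 fell in null and 39 rose in A005B, and its direction in these lines rests on their watered labels. Glyma.15G255700 went from a listed 0 to 13.1 RPKM in null, from 3.71 RPKM in A004A and 2.27 RPKM in B010C to a listed 0, and from 7.71 to 8.40 RPKM in A005B (adjusted p = 0.495). Glyma.17G031100, the only gene called by limma, went from 5.16 to 18.6 RPKM in null and from between 5.50 and 8.44 RPKM to a listed 0 in the transgenic lines (log2 difference of responses -4.69 ± 0.32 SE, adjusted p = 0.0315). There were 0 calls with a mean of at least 5 RPKM, after quantile normalization, without line A004A or without line A005B, and 50 without a filter. At an unadjusted p under 0.05 there were 3289 genes, 9.56% of those tested, and 2159, 1064 and 994 when A004A, A005B and B010C took the place of null. The response differed from that of null by at least 2-fold upward in 1164 genes and downward in 2814 in A004A, in 1697 and 2100 in A005B, and in 1303 and 1064 in B010C. In 580 genes the response of null lay at least 2-fold outside those of the 3 transgenic lines, and the same count was 447 for A004A, 589 for A005B and 433 for B010C. After median-of-ratios scaling the splits against null were 2055 and 1585, 1967 and 1586, and 1664 and 706, and after quantile normalization 2052 and 1748 in A004A and 1934 and 1692 in A005B. With a pseudocount of 0.1 the split in B010C turned to 2303 and 3061.

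The differences of the transgenic lines from null were next compared between lines, which share the null column. In watered leaves, A005B and B010C correlated most across genes (r = 0.63, covariance 0.0908), where simulated unchanged lines gave r = 0.50 and a covariance of 0.0506. A004A correlated with A005B at 0.40 (covariance 0.0637, simulated 0.0498) and with B010C at 0.32 (covariance 0.0450, simulated 0.0509). In dehydrated leaves the pair A004A and A005B stood out, with r = 0.81 and a covariance of 0.265 against a simulated 0.49 and 0.0812. They shared 606 genes at least 2-fold above null and 881 below, against 27.1 and 90.8 for independent lists and 116 and 120 for simulated unchanged lines. A004A with B010C gave r = 0.50 (covariance 0.140, simulated 0.0836), and A005B with B010C 0.42 (covariance 0.101, simulated 0.0814). Null has 1 column per treatment and could not be split, so part of each excess may come from that shared column.

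A comparison free of shared columns sets the watered effect of a line against the dehydrated effect. A004A watered correlated with A004A dehydrated at 0.23 and with A005B dehydrated at 0.24. The same-line value was -0.10 for A005B and -0.08 for B010C, and the remaining pairs of different lines lay between -0.11 and 0.03. Few genes set a line apart in both treatments. Glyma.04G105900 reached 332 RPKM in watered and 59.6 RPKM in dehydrated B010C and at most 2.16 RPKM in any other column. Glyma.13G307500 stood at 15.9 and 7.996 RPKM in A004A and was listed at 0 elsewhere, and Glyma.11G100500 at 12.3 and 3.98 RPKM in A005B and at 0 elsewhere. These genes were chosen after their values were seen, as those with the widest watered gap in their line. Over the 4 lines, 35 genes stood at least 2-fold apart in the same line and direction in both treatments, where pairing watered and dehydrated columns of different lines gave 20 to 50 genes, with a mean of 31.7 over 9 pairings. A further 39 genes were at least 2-fold higher in null and A004A than in the other lines when watered, and in A004A and A005B when dehydrated.

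The last comparison asked whether genes that differed from null before stress were responsive to drying, with the response measured in the other 2 transgenic lines so that no column was shared. The 292 genes higher in watered A004A than in null rose on drying in A005B and B010C by a median of 0.39 on the log2 scale, above all of 10000 random lists matched on expression, whose median was -0.23. The 531 genes lower in A004A had a median of -0.26 (percentile 0.4, random median -0.10). For A005B the median was -0.12 for the 355 higher genes (percentile 97.5) and -0.29 for the 429 lower genes (percentile 34.3). For B010C it was -0.52 for the 192 higher genes (percentile 0.58) and -0.34 for the 374 lower genes (percentile 20.02). For the genes higher in A004A, the alternatives of pseudocount, filter and scaling gave medians from 0.13 to 0.95 and percentiles of at least 99.99. With a pseudocount of 0.1, however, all 6 lists lay at percentile 99.76 or above, so the place of that list was then not particular to it. The medians of the lower genes turned to 0.12 for A004A, 0.30 for A005B and 0.74 for B010C at that pseudocount. Other settings also moved the lists. The genes higher in A005B lay at percentile 81.01 after median-of-ratios scaling and 70.58 after quantile normalization, and the genes lower in A004A at 9.04 after quantile normalization. With a mean of at least 5 RPKM the genes lower in B010C lay at percentile 99.95 and those lower in A005B at 80.54, whereas after quantile normalization they lay at 6.08 and 7.3.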

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

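The tests in this part were chosen after the results were seen, except the regrouping of the 8 columns, which was set before its outcome was seen. In 5 genes null rose at least 2-fold on drying while all 3 transgenic lines fell at least 2-fold, and limma called the difference in 1 of them. Each of the 5 had at least 1 column listed at 0, and their median highest value was 9.47 RPKM. For Glyma.06G150600, Glyma.08G229000, Glyma.15G044100 and Glyma.15G152300 the test of the difference did not pass (adjusted p = 0.494 to 0.536), and 0 genes went the other way. The same search found 3 genes when A004A took the place of null, 4 for A005B and 3 for B010C. For Glyma.17G031100, the gene that was called, limma gave a difference between the responses of -4.69 on the log2 scale, with adjusted p = 0.0315, from 3 transgenic values listed at 0 after drying, and 0 genes were called with a mean of at least 5 RPKM, after quantile normalization, or without line A004A or A005B. When the 8 columns were divided into 4 and 4 in all 35 ways, 1 division, that of dehydrated from watered, called 24237 genes in limma without a line term. The next highest called 4. A share of 1 in 35 is the smallest that this comparison can give, so it argues against chance no further than that. Each other division mixes watered with dehydrated columns. The comparison does not separate drying from anything else that differed between the treatments.

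Glyma.10G011300 was high in A004A and A005B and not in B010C. Scaling of the columns is argued against, since the lowest log2 difference to null in A004A and A005B was 2.26 after quantile normalization. No source pairs the identifier with a name, so whether it counts the over-expressed gene, whether a construct in B010C is counted elsewhere, and whether a column carries a wrong label were not tested and stay open.

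Null had the smallest response to drying, with a slope of 0.83 on the response of the other lines. A scale factor per column shifts log2 values nearly alike and could hardly move this slope, so it was not tested as a cause. A difference in the distribution of values between columns is argued against. The slope was 0.82 after quantile normalization, when the lowest of the other lines was 0.98. Watered null plants already part of the way to the dried state is argued against as the main cause, since the watered column carried 16.4% of the displacement of null along the response of lines not compared. The rest lay in the dehydrated column, whose position was -0.11 for null and between -0.01 and 0.06 for the other lines. Over-expression of the transgene and slower drying of the null plants stay open and cannot be told apart, since with 1 null line the chance that it is the lowest of 4 is 0.25.

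A set of 39 genes was at least 2-fold higher in watered null and A004A than in the other watered lines, and at least 2-fold higher in dehydrated A004A and A005B than in the other dehydrated lines, so that on drying 38 fell in null and 39 rose in A005B. From the sizes of the watered and dehydrated lists, 0.806 genes are expected if genes vary independently. The pattern was the largest found over all combinations of a pair of lines in each treatment, and the next held 3 genes. With 1 column per group, a shift of single columns could move many genes at once, so this number does not exclude chance between columns. Scaling is argued against, since 37 of the 39 genes kept the pattern after quantile normalization. An exchange of the watered labels of null and A005B would make all 39 genes follow A004A and A005B in both treatments, as 2 genes do with the labels as given. With that exchange, Glyma.10G011300 and Glyma.01G082900 would no longer follow these lines, although Glyma.10G011300 has no name here and does not check the labels. The number of genes above all other lines in A005B in both treatments would go from 11 to 3, and 4 genes listed at 0 outside the A005B columns would be divided between lines. Pairings of columns of different lines gave up to 25 and 4 such genes, so neither number marks a line, and the exchange stays open, as does a batch of plants or libraries or a difference in the tissue collected, since the labels give no batch and no biological explanation was tested.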

How the results depend on the processing

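Leaving out a line, and the slopes under other settings, were chosen after seeing the data. No paired analysis was possible over the samples that share replicate numbers, because the table holds 1 column per group. For the same reason leaving out each library was not run. The gene list alternatives (estimated correlation, fry) were not run because no list could be built. The watered and dehydrated columns of a line can be paired, and the dehydration fit did so through its term for line. The limma test of the difference in response did not pair them, and a version paired by line was not run. Depth is unknown, so no limit from counting error can be given. Of 318 values computed under alternatives for 55 results, 239 stayed within 1.5 times the reported count, within 0.1 of the reported log2 value, correlation or slope, or on the same side of the test, and 79 moved further. The 239 include values that could not move, such as the log2 differences of single genes under another filter. Of the 4 named dehydration genes, 0 changed direction. The 6 log2 differences of Glyma.10G011300 to null kept their sign under the 5 alternatives of pseudocount, filter and scaling. Of 30 values, 8 moved by over 0.1, by at most 0.34 (A004A dehydrated, 3.24 to 3.58 after median-of-ratios scaling). The filters could not change the values of a single gene, so only the pseudocount and the scalings tested these differences. The direction of other single genes was not followed. The correlations between line effects and the slopes of the response each stayed within 0.1, with a null slope of 0.82 to 0.84. A scale factor per column could hardly move either, so median-of-ratios scaling tested them little. The log2 changes of the 4 named dehydration genes passed the test with the other pseudocount, filters and scalings and without a trend, and were not refitted without a line. The 2-fold minimum could not remove these genes, since they had been named for the largest changes. The cause of the shifts below was not tested, except that a stricter filter tests fewer genes and a fold minimum removes calls.

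For dehydration over the 4 lines, a mean of at least 5 RPKM gave 13891 calls, of which 7275 were lower, and the 2-fold minimum gave 13089, of which 5518 were higher and 7571 lower. With a mean of at least 5 RPKM, the genes at least 2-fold changed by dehydration numbered 7468 in null, 9687 in A004A, 8862 in A005B and 8787 in B010C.

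For single lines against null in watered leaves, a pseudocount of 0.1 raised the counts to 1841 in A004A, 1962 in A005B and 1558 in B010C, and in dehydrated leaves to 7046, 4410 and 2761. Genes changed the same way in all 3 lines became 253 and 918, and genes with a different response 7664, 7005 and 5364. A mean of at least 5 RPKM lowered the watered counts to 499, 393 and 224, the dehydrated counts to 1178 in A005B and 601 in B010C, those shared by all 3 lines to 24 and 170, and those with a different response to 2497, 2020 and 1390.

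Limma calls for the mean of the 3 lines were few and unstable. In watered leaves there was 1 with a pseudocount of 0.1, 1 without a trend and 40 without a filter, against 0. In dehydrated leaves there were 57 without a filter, 1 with a mean of at least 5 RPKM, 0 without line A004A, 0 without line A005B and 14 without line B010C, against 2. For the difference in response there were 50 without a filter, 0 with a mean of at least 5 RPKM, 0 after quantile normalization, 0 without line A004A, 0 without line A005B and 3 without line B010C, against 1.

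The median dehydration response of genes that differed from null under watering moved with several settings. For genes higher in A004A it was 0.59 with a pseudocount of 0.1, 0.13 without a filter, 0.95 with a mean of at least 5 RPKM, 0.51 after median-of-ratios scaling and 0.28 after quantile normalization. For genes lower in A004A it was 0.12 with a pseudocount of 0.1 and -0.094 after median-of-ratios scaling. For genes higher in A005B it was 0.24 with a mean of at least 5 RPKM and 0.032 after median-of-ratios scaling. For genes lower in A005B it was 0.30 with a pseudocount of 0.1, -0.0056 with a mean of at least 5 RPKM, -0.16 after median-of-ratios scaling and -0.19 after quantile normalization. For genes higher in B010C it was -0.081 with a pseudocount of 0.1, -0.42 without a filter, -0.71 with a mean of at least 5 RPKM, -0.35 after median-of-ratios scaling and -0.39 after quantile normalization. For genes lower in B010C it was 0.74 with a pseudocount of 0.1, 0.35 with a mean of at least 5 RPKM, -0.16 after median-of-ratios scaling and -0.22 after quantile normalization.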

Other observations

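The search for genes that divide the columns was made after the data were seen. The 39 genes that, with the labels as given, followed neither line nor treatment had median values of 10.2 RPKM in watered null, 18.0 in watered A004A, 12.3 in dehydrated A004A and 15.1 in dehydrated A005B, and between 0.544 and 1.69 RPKM in the remaining columns. Glyma.09G278000, among the widest, stood at 274 RPKM in watered and 282 RPKM in dehydrated A004A, 45.0 and 5.28 RPKM in null, 4.74 and 570 RPKM in A005B, and 4.10 and 3.04 RPKM in B010C. Dehydrated columns also fell into pairs more widely. In 280 genes A004A and A005B lay at least 2-fold above null and B010C after drying, and in 236 genes below them, against 14 to 58 genes in each direction for the other pairings of dehydrated lines. In watered leaves the pair null and A004A lay at least 2-fold above A005B and B010C in 99 genes and below in 34, and the other pairings gave 10 to 23.

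In B010C a gene near Glyma.04G105900 in identifier order, Glyma.04G105500, was also high in that line alone, at 9.24 RPKM watered and 3.12 RPKM dehydrated and at most 0.242 RPKM elsewhere. In A005B the neighbouring identifiers Glyma.09G051200 and Glyma.09G051300 were both above the other lines in both treatments, the first at 16.04 and 10.4 RPKM against at most 6.67, the second at 4.60 and 2.20 RPKM and listed at 0 elsewhere.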
